A study of Mus musculus with 21 samples.

How the data were processed

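The data were 21 protein binding microarrays in 10 groups, each group 1 protein on 1 form of cytosine. The proteins were the DNA-binding domains of the bZIP factors CEBPB and CREB1 and of the mutants CEBPB(V285A) and CREB1(A297V), made with a GST tag by in vitro transcription and translation. The second strand of the arrays was synthesised with cytosine (C), 5-methylcytosine (5mC) or 5-hydroxymethylcytosine (5hmC), so that the modified base lay on the synthesised strand alone. CREB1, CEBPB(V285A) and CREB1(A297V) were analysed on all 3 forms and CEBPB on 5hmC. Each group had 2 arrays, except CREB1 5mC with 1 and CREB1(A297V) 5hmC with 4.

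The deposited matrix held a score per array for each of 65535 sequences of 8 bases (8-mers), a Z-score made by the authors, with a median within 0.001 of 0 in every array. How the authors turned probe signals into Z-scores was not stated, and the Z-scores were not scaled between arrays, so they measured relative preference and not affinity. Their range differed widely: the largest Z-score of an array was 256 on a CEBPB(V285A) 5mC array and 15.7 on a CREB1(A297V) 5hmC array. The deposited signal files held, per the file headers, the median intensity of each of 40330 spots and of its local background, not background-subtracted. A probe carried 35 variable bases, and an 8-mer had a median of 17 probes and at most 41. The matrix held a Z-score of 0 for 409 8-mers that no probe carried. Another 286 8-mers had 1 probe. Of the 1024 8-mers with fewer than 8 probes, all but 4 contained CCCC.

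The strand on which the 8-mers were written was checked by correlating the deposited Z-scores with the median probe intensity of each 8-mer, under 4 readings of the printed sequence. The name in the matrix was the printed sequence read backwards (Pearson r across 8-mers 0.603 to 0.986 in the 21 arrays, against at most 0.819 for any other reading). All 8-mers are therefore given here as their complement. This is the sequence of the synthesised strand from 5′ to 3′, with every C in a name modified on the 5mC and 5hmC arrays, if the printed sequence is the template for primer extension, read from 5′ to 3′. That was assumed, since each printed sequence was followed by a constant linker, and was not tested. If the printed sequence were the synthesised strand, each list would trade places with its reverse complements and every asymmetry would change sign.

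The main analysis used limma 3.58.1 in R 4.3.3 on the deposited Z-scores, with 1 coefficient per group, all 21 arrays in a single fit (11 residual degrees of freedom) and a mean-variance trend in the empirical Bayes step. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 8-mers of a comparison, and an 8-mer was called at an adjusted p under 0.05. Between groups, the arrays did not overlap in any called 8-mer, except in 3 of the 5745 for CREB1(A297V) against CREB1 on 5hmC. Chance gives such a separation for 1 in 3 8-mers with 2 arrays against 2. CREB1 on 5mC, with 1 array, was assumed to vary like the other groups, so its p-values and calls do not test that array. The fit used 1 spread per 8-mer for all groups, although spreads differed. The SD of TGACGTCA was 24.9 for CREB1 and 0.249 for CREB1(A297V), both on C. Changes in groups with a small spread can therefore be missed, and those in groups with a wide spread called too readily. Nothing in the labels said that replicate arrays came from separate protein preparations, so every p-value measured only the spread between these arrays. Comparisons were each mutant against CREB1 on each cytosine form, CEBPB(V285A) against its wild type CEBPB and CEBPB against CREB1 on 5hmC, and each modified form against C within a protein. Interaction contrasts tested whether the effect of 5mC or 5hmC differed between a mutant and CREB1.

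These comparisons, the lists, the names and most of the other scales and models were fixed before the data were examined. Named 8-mers were 11 fixed sites: the 9 combinations of the cores GTCA (CRE), GCAA (C/EBP) and GTAA (PAR), and the composite site TGATGCAA with its reverse complement TTGCATCA. Further names were, per comparison, up to 5 called 8-mers with the largest rise and up to 5 with the largest fall among those whose groups did not overlap, and per group the 3 with the highest mean, skipping any that was the reverse complement of, or shared 7 bases in a row with, one already named. There were 17 fixed lists. Of these, 10 had 64 members that ended or began with a 5-base core: NNNCGTCA, NNNCGCAA, NNNCGTAA, NNNTGCAA and NNNTGTCA, and their reverse complements TGACGNNN, TTGCGNNN, TTACGNNN, TTGCANNN and TGACANNN. The others were AP-1 (TGACTCA or TGAGTCA, 16 8-mers), C/EBP-ATF composite (TGATGCA, GATGCAA, TTGCATC or TGCATCA, 30 8-mers), E-box (CACGTG, 48 8-mers), ETS (CCGGAA or TTCCGG, 95 8-mers), A and T only (255 8-mers), background with CG (22476 8-mers) and background without CG (35208 8-mers, with C or G). Neither background list contained any of the 3 cores or their reverse complements. The last 5 lists served as controls. Members of a list overlap and share probes, so a list was tested by limma on its mean Z-score per array, adjusted over lists and comparisons. Strand asymmetry was the mean Z-score of a list minus that of its reverse complements, 1 value per array, tested in the same way over 5 asymmetries.

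In a simulation, 50 8-mers per shift were raised or lowered in replicate noise with the spread of the arrays. Its false calls hold for that noise, not for differences between runs. For CEBPB(V285A) against CREB1 on C, 22% of shifts by 2 Z, 86% by 4 Z, 98% by 8 Z and 100% by 16 Z were recovered, with 7 of 65335 unchanged 8-mers called. For CREB1 on 5mC against C, these were 8%, 58%, 100% and 100%, with 4 unchanged 8-mers called, and for CREB1(A297V) on 5hmC against C 38%, 92%, 98% and 100%, with 6 called. A shift of 2 Z added to 1 asymmetry was estimated at 1.69 and called in 1 of the 4 comparisons with that group and in 0 of the other 66 tests. The median spot signal was 0.960 to 5.85 times the median background, lowest on CREB1(A297V) 5hmC replicate 2, where 56.1% of spots lay at or below their own background. Few arrays limit the precision of every comparison.

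A number in the deposited name of each array was taken as its run, which gave 6 runs. The sample titles did not name a run, so that reading was assumed. CREB1 C and CREB1 5mC shared 1 run with CREB1(A297V) C, CREB1(A297V) 5mC and replicates 1 and 2 of CREB1(A297V) 5hmC. CEBPB 5hmC and CREB1 5hmC shared another. A further run held both CEBPB(V285A) 5hmC arrays and replicate 4 of CREB1(A297V) 5hmC, replicate 3 of which was alone in its run. CEBPB(V285A) C and CEBPB(V285A) 5mC each had a run to themselves. The spots lay in 1 of 2 layouts, and both CREB1 5hmC arrays and replicates 1 and 2 of CREB1(A297V) 5hmC had the layout that the other 17 arrays lacked.

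The same comparisons were rerun on other scales and models: Z-scores recomputed from the probe intensities (median ln intensity of the probes of an 8-mer, centred and scaled by the median absolute deviation), the same after normexp background correction with offset 50, the asinh of the deposited Z-scores, quantile normalization between arrays, a minimum group mean Z-score of 3, a replicate block, run as a fixed or as a random block, and leaving out each array in turn. Where 1 array is named without which a call ended, it is the array with the highest adjusted p, and results that lost their call without any of several arrays, many of them outside the comparison, are given with the number of those arrays. Profiles were also compared over the highest 50 and 500 8-mers in place of 100, from recomputed Z-scores and after averaging both strands. Chosen after seeing the data were a minimum of 8 probes, the arrays of 1 run alone, and leaving out the 2 dimmest CREB1(A297V) 5hmC arrays. Nothing in the labels said that replicate numbers pair the arrays. Residuals of arrays with the same number correlated across 8-mers between -0.381 and 0.206 (median 0.0364) in 36 pairs of groups, 9 of them over 0.1 and 2 under -0.1. Those over 0.1 included the 3 pairs among the CREB1(A297V) groups (0.149, 0.190 and 0.206), so a pairing there was not excluded. The software was data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with matplotlib 3.10.9 for plots. Another 10 columns of the matrix were empty and were not used here. CEBPB on C or 5mC was not analysed here.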

Results

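The 3 8-mers named for each group leave out any that shares 7 or 8 bases in a row, on either strand, with a higher one. Those named for each comparison, besides the fixed 8-mers, leave them out too, and were called over all 8-mers. On C, CREB1 gave its highest Z-scores to the CRE palindrome TGACGTCA (195 ± 24.9, mean ± SD of 2 arrays) and to GTGACGTA (107) and TATGACGT (76.6). CEBPB(V285A) gave its highest to the PAR palindrome TTACGTAA (241 ± 13.2), TGACGTAA (192 ± 27.0, reverse complement TTACGTCA 167 ± 25.0) and TGACGTCA (155 ± 27.9). CREB1(A297V) ranked TTACGTAA first on all 3 forms of cytosine, with 55.1 ± 10.8 on C, 49.0 ± 4.11 on 5mC and 21.7 ± 4.17 on 5hmC (4 arrays). On C these were followed by TGACGTAA (37.4, reverse complement TTACGTCA 26.7) and TTACATAA (23.9), and on 5mC by TGACGTAA (40.1) and TGTCGTAA (21.3). On 5mC, the single CREB1 array was highest at CTACGCAA (104), ACGCAATA (75.2) and TGACGCAA (58.2), and CEBPB(V285A) at TTACGCAA (253 ± 3.33), TGACGCAA (221 ± 22.9) and ACGCAATC (217). On 5hmC, CREB1 was highest at the composite site TGATGCAA (156 ± 20.6), TGACGCAA (76.4 ± 8.97) and ACGCAATA (75.6), and CEBPB(V285A) at TTATGCAA (177), TTATGTAA (158) and TTACGCAA (141 ± 75.1). CEBPB on 5hmC had TCCCCATA (59.6) and CCCCGTCG (43.7), each carried by 1 probe, above TTGCGTAA (35.7 ± 13.2). CREB1(A297V) on 5hmC had CCCCCGGC, also with 1 probe, at 18.3 ± 13.1 (4 arrays), between TTACGTAA and TTAGGTAA (17.8).

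Among the 100 8-mers with the highest group mean, 93 held GTCA or TGAC for CREB1 on C, 17 on 5mC and 50 on 5hmC. Those with GCAA numbered 1 on C, 74 on 5mC and 35 on 5hmC for CREB1, and 4, 92 and 29 for CEBPB(V285A). The reverse complement TTGC was in at most 4 of the 100 in every group except CEBPB on 5hmC, where it was in 25 and GCAA in 12. For CREB1(A297V), GTAA or TTAC was in 68 on C, 87 on 5mC and 75 on 5hmC. The CRE palindrome TGACGTCA ranked 1 on C, 30 on 5mC and 35 on 5hmC for CREB1, and 4, 260 and 351 for CEBPB(V285A). For CREB1(A297V) its rank was 6 on C, 157 on 5mC and 16145 on 5hmC, and for CEBPB on 5hmC it was 374. Z-scores were relative within an array, so these ranks do not compare affinities between proteins.

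**Figure D1:**
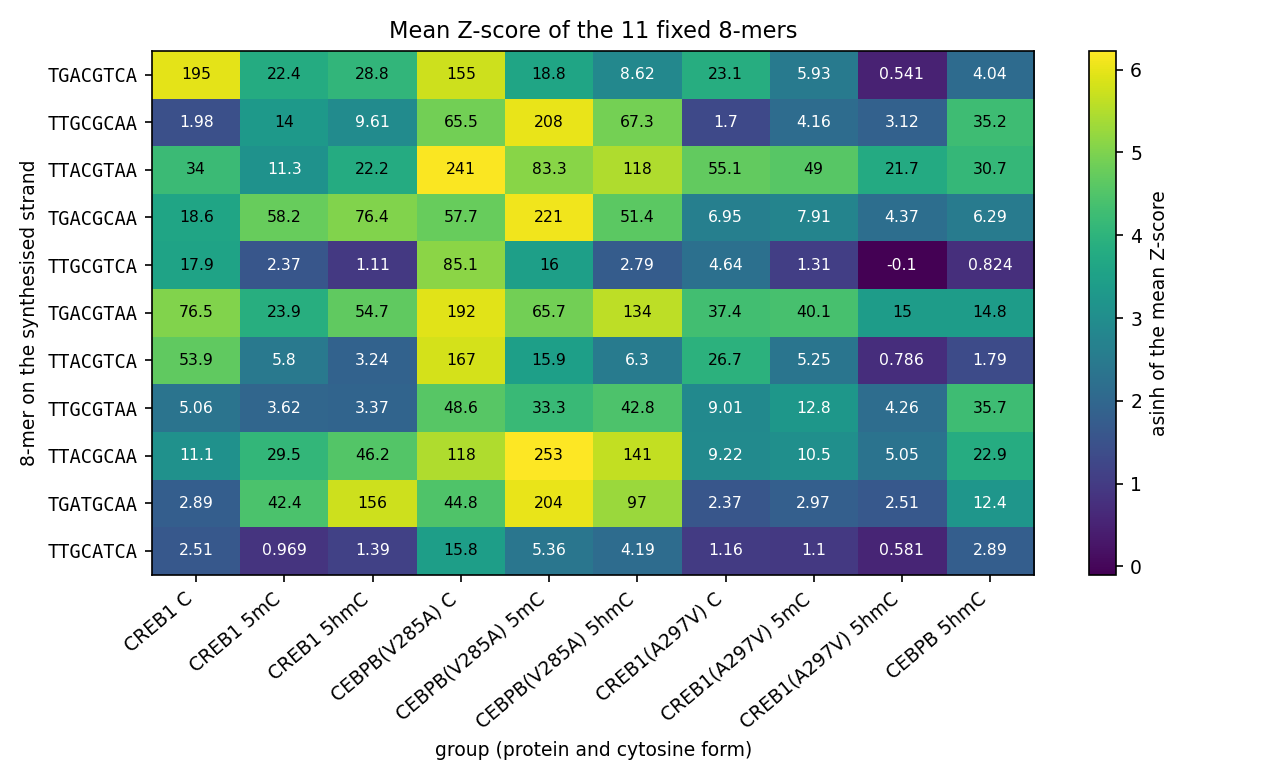
Mean Z-score of the 11 fixed 8-mers (vertical) in the 10 groups of arrays (horizontal), with the mean in each cell and colour on an asinh scale. TGACGTCA was at 195 for CREB1 on C and 0.541 for CREB1(A297V) on 5hmC, and TGATGCAA was at 2.89 for CREB1 on C and 156 on 5hmC.

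On C, CEBPB(V285A) had higher Z-scores than CREB1 at 8 of the 11 fixed 8-mers, lower at 0, with 3 not called (10 higher and 1 lower adjusted over the list alone). None of the 8 was called after normexp. The largest difference was at TTACGTAA, 241 ± 13.2 against 34.0 ± 5.14 (difference 207, adjusted p 3.0e-08). TTACGCAA was at 118 ± 13.0 against 11.1 ± 1.18 (107, adjusted p 0.022) and the C/EBP palindrome TTGCGCAA at 65.5 ± 0.249 against 1.98 ± 0.120 (63.5, adjusted p 0.0011). TTGCGTCA (67.2, adjusted p 3.9e-06), TTGCGTAA (43.5, 0.026), TGATGCAA (41.9, 0.035) and TTGCATCA (13.3, 1.8e-06) were also higher. TTACGTCA was higher by 113 (adjusted p 3.8e-05), a direction that flipped after normexp background correction (-0.354). TGACGTCA itself was not called, at 155 ± 27.9 against 195 ± 24.9 (adjusted p 0.23). Neither were TGACGCAA (57.7 ± 4.35 against 18.6 ± 2.55, 0.070) and TGACGTAA (192 ± 27.0 against 76.5 ± 10.2, 0.087).

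TTACGNNN, NNNCGCAA and TTGCGNNN were higher in CEBPB(V285A) on all 5 scales, and NNNCGTAA on all but normexp, where it was not called. TTACGNNN was higher by 10.1 (14.6 ± 1.38 against 4.51 ± 0.798, adjusted p 1.9e-07), with 17 of 64 8-mers higher and 0 lower (27 higher adjusted over the list alone). NNNCGTAA was higher by 8.53 (13.5 ± 1.05 against 4.93 ± 0.692, 1.4e-05; 8 of 64, 24 adjusted over the list alone), NNNCGCAA by 4.29 (5.65 ± 0.294 against 1.35 ± 0.132, 8.0e-05; 3 of 64, 5 adjusted over the list alone) and TTGCGNNN by 3.73 (4.33 ± 0.354 against 0.600 ± 0.307, 8.9e-06; 7 of 64, 13 adjusted over the list alone). NNNCGTCA was higher by 6.22 (19.5 ± 4.29 against 13.3 ± 1.49, 0.0015; 19 of 64), but by 3.19 without CEBPB(V285A) C replicate 1, and it was lower after normexp (-0.625) and quantile normalization (-0.354). TGACGNNN was higher by 4.85 (0.013; 7 of 64; 1.95 and 7.75 without CEBPB(V285A) C replicates 1 and 2), again lower after normexp (-1.12) and quantile normalization (-1.76). TTGCANNN (1.87, adjusted p 0.00041), NNNTGTCA (1.58, 1.6e-05), AP-1 (1.34, 0.00036) and the C/EBP-ATF composite list (3.03, 0.010) were higher, as was TGACANNN (1.42, 0.00091), whose direction flipped after normexp (-0.156). NNNTGCAA was not called (1.85, 0.094), and neither was any control list: E-box 0.834 (0.056), ETS -0.243 (0.20), A and T only 0.457 (0.22), background with CG 0.0169 (0.91) and background without CG 0.00114 (0.99).

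Over all 8-mers, 607 were called between CEBPB(V285A) and CREB1 on C, 582 higher and 25 lower. Of the higher ones 369 held CG, and 316 of the 607 differed by at least 5 Z. Of the lower ones, 15 lay in the background list with CG and 9 in that without, and the largest differences named were AACGTACT -4.25, AAAACGAA -4.14, AAAGAAGG -3.35, AGAAGGGT -2.69 and ACGACAGA -2.68. The count was 185 without replicate 1 of CREB1 on C and 254 without replicate 1 of CEBPB(V285A) on C. Leaving out 1 array also removed the calls of TTGCGTAA (42.9, adjusted p 0.239) and TGATGCAA (40.7, 0.290), both without CREB1 C replicate 1, of TTACGCAA (98.1, 0.266, without CEBPB(V285A) C replicate 1), and of all 5 lower 8-mers (AACGTACT -3.79, 0.197; AAAACGAA -3.22, 0.233; AGAAGGGT -2.52, 0.311; ACGACAGA -2.60, 0.323, all without CREB1 C replicate 1, and AAAGAAGG -3.04, 0.264, without CEBPB(V285A) C replicate 1). It removed those of the list TGACGNNN (1.95, 0.152, without CEBPB(V285A) C replicate 1) and of the composite list (2.81, 0.0577, without CREB1 C replicate 1). Calls ended without any of 16 arrays at ACGACAGA, 9 at TGATGCAA, 7 at AGAAGGGT, 5 at TTGCGTAA, 4 at TTACGCAA and AAAGAAGG, 3 at AACGTACT and 2 at AAAACGAA and TGACGNNN. Most calls were lost on other scales. After normexp 1 8-mer was called. On the asinh scale 116 were called (113 higher and 3 lower), without TTGCGTCA, TTACGTCA and TTGCATCA. Recomputed Z-scores gave 240 (239 higher and 1 lower), without TTACGTAA, and quantile normalization 16 (10 higher and 6 lower), without TTGCGCAA, TTACGTCA, TTGCGTAA and TGATGCAA. The groups were in different runs, so a difference between runs and a difference between the proteins cannot be told apart here.

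**Figure D2:**
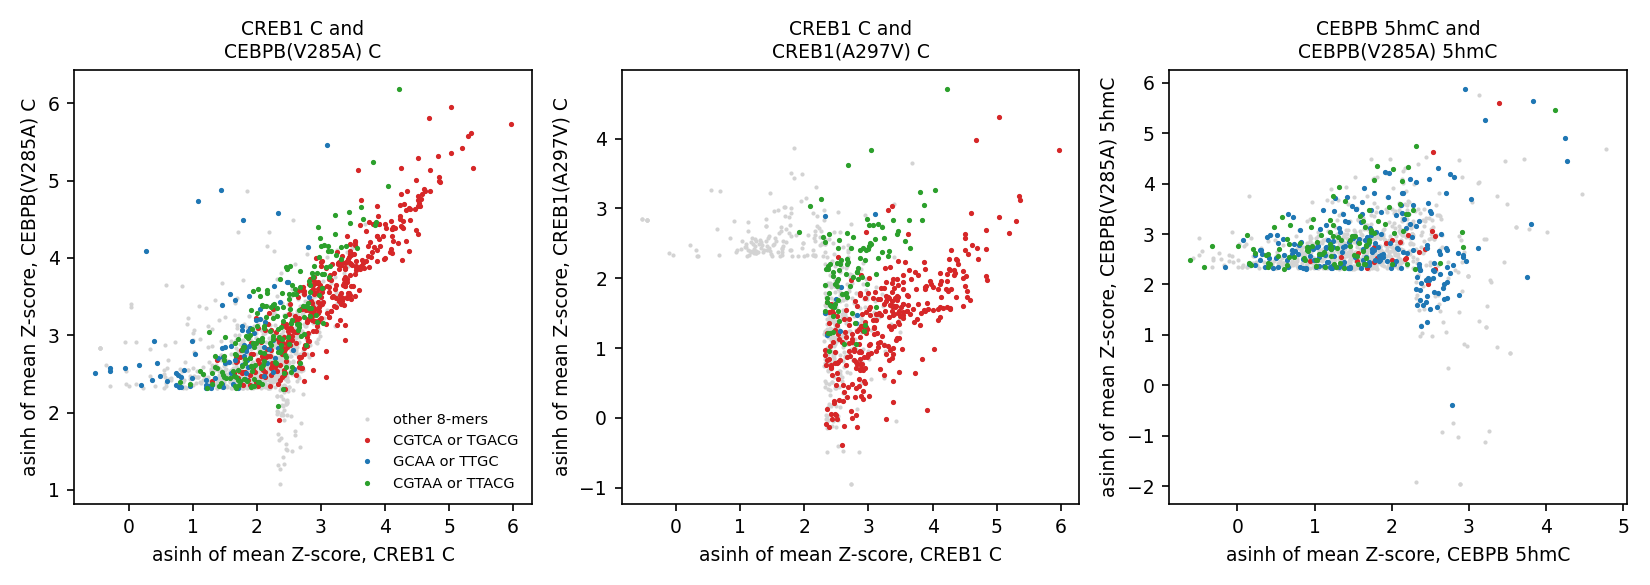
Mean Z-score (asinh scale on both axes) of 8-mers with a group mean of at least 5 in 1 of the 2 groups drawn, for CREB1 against CEBPB(V285A) on C, CREB1 against CREB1(A297V) on C, and CEBPB against CEBPB(V285A) on 5hmC. 8-mers with CGTCA or TGACG are red, with GCAA or TTGC blue, with CGTAA or TTACG green and others grey, and the pairs of groups shared 77, 19 and 24 of their 100 highest 8-mers.

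CREB1(A297V) and CREB1 on C shared a run, and the CRE lists were lower in the mutant. NNNCGTCA was lower (difference -11.3, 1.97 ± 0.511 against 13.3 ± 1.49, adjusted p 1.3e-05), with 40 of 64 8-mers lower, 0 higher and 24 not called (55 lower adjusted over the list alone). TGACGNNN was lower (difference -12.0, 2.59 ± 0.561 against 14.6 ± 1.87, 1.6e-05), with 41 of 64 lower and 0 higher (58 lower adjusted over the list alone). TGACGTCA was the only fixed 8-mer called of 11, at 23.1 ± 0.249 against 195 ± 24.9 (difference -172, adjusted p 7.7e-06). Adjusted over the list alone, TTGCGTCA was lower too (-13.3, p 0.046). The PAR lists were not called, NNNCGTAA at 3.79 ± 0.118 against 4.93 ± 0.692 (adjusted p 0.38; 3 of 64 lower) and TTACGNNN at a difference of -0.970 (0.30; 2 higher and 4 lower). TTACGTAA was at 55.1 ± 10.8 against 34.0 ± 5.14 (0.32). Of the called 8-mers that were higher, the largest differences were at ATTACACA (16.7 against 2.91), TTACCTAA (12.5), TTACGACA (11.5, but 6.995 without CREB1(A297V) C replicate 2), TGTCGACA (7.71) and ATTACTAA (7.35).

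The E-box list was also lower in CREB1(A297V) (difference -2.70, 0.629 ± 0.194 against 3.33 ± 0.496, adjusted p 1.8e-05; 18 of 48 8-mers, 46 adjusted over the list alone). NNNTGTCA (-1.20, 0.00016), AP-1 (-0.985, 0.0033) and background with CG (-0.334, 0.0086) were lower. TGACANNN was lower (-0.968, 0.011), a direction that flipped after quantile normalization (0.0793). NNNCGCAA (-0.579, 0.48), ETS (0.188, 0.32), A and T only (0.331, 0.39) and background without CG (0.0707, 0.58) were not called. Of 1003 called 8-mers 71 were higher and 932 lower, 860 of the lower ones held CG, and 340 of all differed by at least 5 Z. Among called 8-mers, the largest falls after TGACGTCA were at GTGACGTA (-95.7), TGACGTGG (-46.1), AATGACGT (-35.4) and CGTCATCG (-34.6). The count was 223 without CREB1 C replicate 2, and 331 and 348 without CREB1(A297V) C replicates 1 and 2. Without CREB1 C replicate 2, TTACGACA (12.05, adjusted p 0.0593), CGTCATCG (-26.3, 0.481), TGACANNN (-0.716, 0.108) and background with CG (-0.269, 0.068) were no longer called. CGTCATCG lost its call without any of 7 arrays and TGACANNN without any of 2. With recomputed Z-scores 963 8-mers were called (167 higher and 796 lower), and on the asinh scale 594 (150 higher and 444 lower). With the 9 arrays of this run alone, 295 were called (9 higher and 286 lower).

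For CREB1, 5mC against C was compared within 1 run, with 1 array on 5mC. The p-values and calls here therefore do not test that array. NNNCGCAA rose by 9.16 (10.5 against 1.35 ± 0.132). Its reverse complements TTGCGNNN were not called (-0.0128). NNNTGCAA, with no CG in its core, rose by 4.09 (4.62 against 0.535 ± 0.0185), and TTGCANNN was not called (0.984). Both CRE lists fell: NNNCGTCA (difference -11.1, 2.20 against 13.3 ± 1.49) and TGACGNNN (difference -9.51, 5.10 against 14.6 ± 1.87). TGACGTCA fell by 173 to 22.4 (adjusted p 6.6e-05), the only call among the 11 fixed 8-mers. Adjusted over the list alone, TGACGCAA (39.6) and TGATGCAA (39.5) rose and TTACGTCA and TTGCGTCA fell as well.

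Among 8-mers called over all 8-mers, the largest rises of CREB1 with 5mC were at CTACGCAA (104 against 4.43, adjusted p 0.00052), ACGCAATA (69.2), CGACGCAA (43.8), CCACGCAA (28.2) and CCCGCAAT (24.3), and the largest falls after TGACGTCA were at TACGTCAC (-94.8), TGACGTGG (-43.7), AATGACGT (-34.3) and CAACGTCA (-31.9). TTACGNNN (-2.37, 0.045), NNNTGTCA (-1.15, 0.0011), TGACANNN (-1.40, 0.0041), AP-1 (-0.939, 0.015) and E-box (-1.71, 0.0033) fell, and the composite list rose (3.57, 0.013). NNNCGTAA (-2.02, 0.20), ETS (-0.115, 0.63), A and T only (-0.441, 0.35) and both background lists (-0.0329, 0.85 with CG and -0.118, 0.43 without) were not called. Of 541 called 8-mers 271 rose and 270 fell, and 303 changed by at least 5 Z. Without CREB1 C replicate 2, 218 were called, and the calls of ACGCAATA (70.3, adjusted p 0.109), CGACGCAA (43.5, 0.23), CCACGCAA (28.5, 0.0578), TGACGTGG (-35.0, 0.106), CAACGTCA (-29.7, 0.23), TTACGNNN (-1.81, 0.178) and AP-1 (-0.664, 0.104) were lost. Those of CAACGTCA, CGACGCAA, TTACGNNN and ACGCAATA were lost without any of 18, 16, 15 and 2 arrays. The composite list was not called without CREB1 C replicate 1 (3.35, 0.0505). Recomputed Z-scores gave 785 calls (520 higher and 265 lower), normexp 453 (123 higher and 330 lower) and asinh 100 (67 higher and 33 lower).

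For CEBPB(V285A), 5mC raised nearly every 8-mer of NNNCGCAA: 63 of 64 rose and 0 fell (63 adjusted over the list alone), and the list rose by 27.9 (33.6 ± 0.808 against 5.65 ± 0.294, adjusted p 1.9e-12). NNNTGCAA rose by 17.2 (19.6 ± 1.72 against 2.39 ± 0.0420, 5.4e-09; 55 of 64, 58 adjusted over the list alone). NNNCGTCA fell by 17.7 (1.83 ± 0.0677 against 19.5 ± 4.29, 2.4e-07; 58 of 64, 62 adjusted over the list alone), as did TGACGNNN (difference -11.9, 7.55 ± 0.548 against 19.5 ± 4.10, 1.6e-05; 46 of 64 lower and 2 higher, 54 and 2 adjusted over the list alone). Of the 11 fixed 8-mers 4 rose and 6 fell, also adjusted over the list alone. TGACGCAA rose by 164 (221 ± 22.9 against 57.7 ± 4.35, 2.4e-08), TGATGCAA by 159.6 (204 ± 3.89 against 44.8 ± 4.00, 1.9e-08), TTGCGCAA by 142 (208 ± 10.7 against 65.5 ± 0.249, 2.8e-08) and TTACGCAA by 135 (0.00061). TTACGTCA fell by 151 (15.9 ± 1.44 against 167 ± 25.0, 1.1e-07), as did TGACGTCA (difference -136, 18.8 ± 3.89 against 155 ± 27.9, 3.7e-06), TGACGTAA (-126, 0.012), TTGCGTCA (-69.1, 7.9e-08) and TTGCATCA (-10.5, 5.9e-07). TTACGTAA fell by 158 (83.3 ± 8.59 against 241 ± 13.2, 1.0e-08), a direction that flipped after normexp (0.931). TTGCGTAA was not called (-15.3, 0.47).

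With 5mC in CEBPB(V285A), TTGCGNNN (2.06, adjusted p 0.0010; 11 higher and 3 lower), TTGCANNN (2.01, 0.00023; 14 higher and 2 lower) and the composite list (18.5, 4.2e-09; 11 of 30 higher and 6 lower) rose. TTACGNNN (-6.01, 1.7e-05; 21 of 64 lower and 4 higher), NNNTGTCA (-2.62, 1.9e-07), TGACANNN (-1.99, 6.1e-05), AP-1 (-2.62, 1.2e-06) and E-box (-3.52, 1.9e-06; 33 of 48 lower) fell, as did NNNCGTAA (-6.51, 0.00013), which rose after normexp (0.138). ETS (-0.00186, 0.99), A and T only (-0.0810, 0.86), background with CG (-0.144, 0.22) and background without CG (0.0653, 0.61) were not called. Among called 8-mers, the largest rises outside the fixed ones were at ACGCAATC (217 against 17.2), CTACGCAA (181) and TTATGCAA (156), and the largest falls at ACGTCACA (-100.5) and GATGACGT (-92.0, but -58.1 without CEBPB(V285A) C replicate 1). In all, 1972 8-mers rose and 2287 fell, 1513 of these 4259 by at least 5 Z. Without CEBPB(V285A) C replicate 1, 2557 were called and TGACGTAA was not (-107, adjusted p 0.152; lost without any of 3 arrays). After normexp 2523 were called (1590 higher and 933 lower). Each group filled its own run, so run and cytosine form cannot be told apart.

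For CREB1(A297V), compared within 1 run, 5mC changed 22 8-mers, 13 up and 9 down, and none of the 17 lists. The rises were small, at ATCGTAAT (6.11), GCTACATA (3.56), CCACTACA (3.18), CGCTACAA (3.04) and CCAACTGC (3.01). The falls were at TTACGACA (-15.9), TTACCTAA (-11.8), TGTCGACA (-8.57), TTACACAT (-7.30) and TTACCTCA (-6.33). Of the 11 fixed 8-mers 0 were called, also adjusted over the list alone, with TTACGTCA at 5.25 ± 3.23 against 26.7 ± 3.20 (adjusted p 0.45) and TGACGTCA at 5.93 ± 4.60 against 23.1 ± 0.249 (0.68). NNNCGTAA was at 6.32 ± 1.92 against 3.79 ± 0.118 (0.055; 0 of 64 called, 20 higher adjusted over the list alone), and NNNCGCAA and NNNCGTCA were not called (1.19, 0.15 and -1.40, 0.42). The count of 22 was unstable. It was 96 without CREB1(A297V) 5mC replicate 1, 0 without its replicate 2 (limma; 5307 at an unadjusted p under 0.05) and 5 without CREB1(A297V) C replicate 2. It was also 13 without either CREB1 C array, 13 and 14 without CEBPB(V285A) C replicates 1 and 2, and 14 without either CREB1 5hmC array, and none of the 10 named 8-mers was called without CREB1(A297V) 5mC replicate 2 (TTACGACA -15.1, adjusted p 0.129). CCACTACA lost its call without any of 6 arrays, ATCGTAAT, GCTACATA and CGCTACAA without any of 3, and CCAACTGC and TTACCTCA without any of 2. With a replicate block 64 were called (50 higher and 14 lower), and with the arrays of this run alone limma called 0 (6256 at an unadjusted p under 0.05). Recomputed Z-scores gave 72 calls (64 higher and 8 lower), normexp 1 (1 higher), asinh 2 (2 higher) and quantile normalization 234 (164 higher and 70 lower).

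With 5mC, NNNCGCAA rose by more than its reverse complements. The asymmetry of CGCAA, NNNCGCAA less TTGCGNNN, was 0.751 ± 0.175 for CREB1 on C and 9.92 on the single 5mC array, a rise of 9.17. For CEBPB(V285A) it rose from 1.31 ± 0.0607 to 27.2 ± 0.536, by 25.9 (SE 0.489, adjusted p 9.4e-19). In CREB1(A297V) it was not called (0.571 ± 0.0736 and 1.66 ± 0.676, 0.072), but the asymmetry of CGTAA rose by 3.29, from 0.249 ± 0.288 to 3.53 ± 1.57 (7.4e-05; by 2.18 without CREB1(A297V) 5mC replicate 2). The asymmetry of TGCAA rose with 5mC by 3.10 in CREB1 and 15.2 in CEBPB(V285A) (2.2e-12). That of CGTCA fell by 5.75 in CEBPB(V285A) (3.4e-08) and was not called in CREB1 (-1.56). With 5hmC, the asymmetry of CGCAA rose by 3.93 in CREB1, to 4.68 ± 0.579 (1.1e-06), and by 2.96 in CEBPB(V285A), to 4.27 ± 0.686 (3.8e-05), and it was not called in CREB1(A297V) (-0.225, 0.73). The asymmetry of CGTCA moved towards TGACGNNN with 5hmC, by -7.07 in CREB1 (1.7e-09) and -4.02 in CEBPB(V285A) (3.4e-06). TGCAA rose by 5.30 in CREB1 (3.8e-06) and 5.28 in CEBPB(V285A) (3.8e-06), and CGTAA by 2.91 in CEBPB(V285A) (0.00027). On C, CGTCA was higher (1.37, 0.043) and CGTAA lower (-1.60, 0.028) in CEBPB(V285A) than in CREB1, which were not called without CREB1 C replicate 2 (CGTCA, 1.10, 0.217; 10 arrays in all) and CEBPB(V285A) C replicate 1 (CGTAA, -1.36, 0.146; 3 in all).

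**Figure D3:**
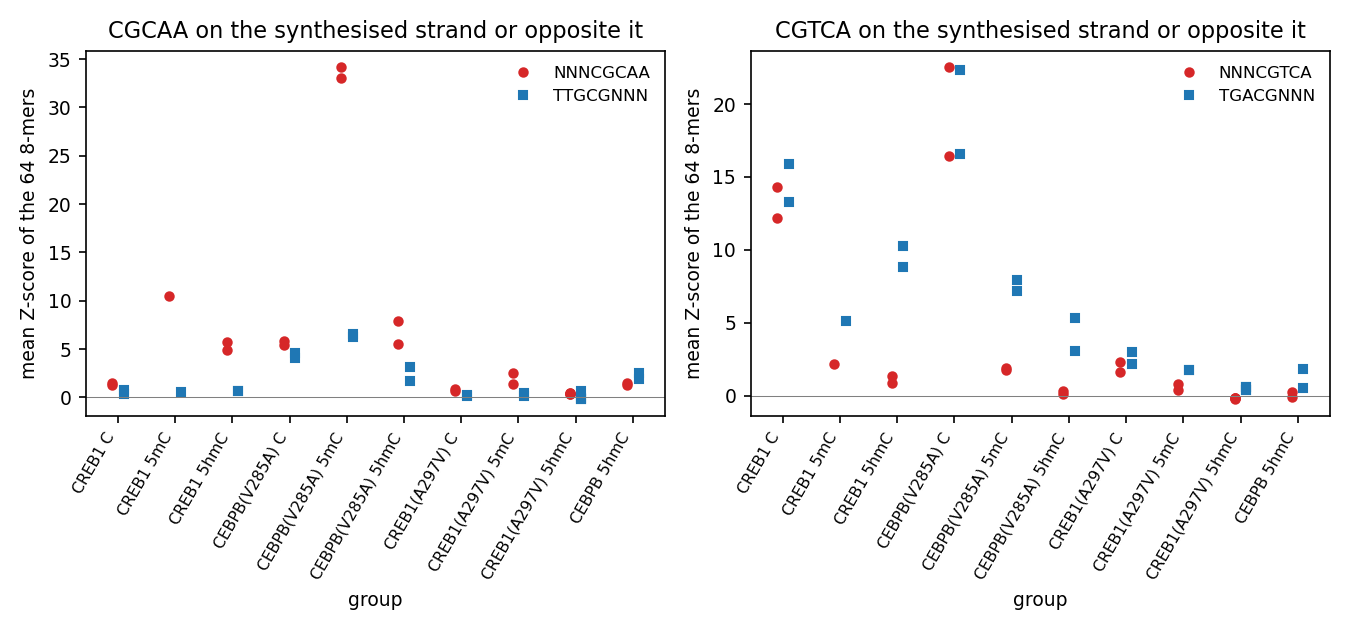
Mean Z-score (vertical) of NNNCGCAA and TTGCGNNN (left) and of NNNCGTCA and TGACGNNN (right) in each array, by group (horizontal). On 5mC, NNNCGCAA was at 33.6 ± 0.808 for CEBPB(V285A) and 10.5 for CREB1 (1 array), and on 5hmC TGACGNNN was at 9.53 ± 1.01 and NNNCGTCA at 1.12 ± 0.313 for CREB1.

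With 5hmC, the CRE lists of CREB1 fell and the lists with GCAA rose. NNNCGTCA fell by 12.2 (1.12 ± 0.313 against 13.3 ± 1.49, adjusted p 7.4e-06), with 50 of 64 8-mers lower and 0 higher (57 lower adjusted over the list alone). TGACGNNN fell by 5.08 (9.53 ± 1.01 against 14.6 ± 1.87, 0.010), with 17 of 64 lower and 11 higher (24 and 13 adjusted over the list alone). NNNTGCAA rose by 7.17 (7.71 ± 0.846 against 0.535 ± 0.0185, 1.4e-05; 31 of 64, 48 adjusted over the list alone), NNNCGCAA by 3.97 (5.32 ± 0.564 against 1.35 ± 0.132, 0.00016; 10 of 64, 11 adjusted over the list alone) and the composite list by 11.3 (12.6 ± 1.45 against 1.27 ± 0.316, 2.9e-07; 13 of 30 higher and 1 lower). TGATGCAA rose by 153 (156 ± 20.6 against 2.89 ± 1.71, 1.5e-06) and TGACGCAA by 57.8 (76.4 ± 8.97 against 18.6 ± 2.55, 0.0021). TGACGTCA fell by 166 (28.8 ± 13.7 against 195 ± 24.9, 5.8e-06), as did TTACGTCA (-50.7, 0.0065) and TTGCGTCA (-16.8, 0.027), so that 2 of 11 fixed 8-mers rose and 3 fell, also adjusted over the list alone. The reverse complement of the composite site, TTGCATCA, was not called (1.39 ± 0.187 against 2.51 ± 0.104). Further rises were at ACGCAATA (69.6), ATGCAATA (43.5 against -0.298) and CGATGACG (40.1, which flipped after normexp, -0.574). Further falls were at TACGTCAC (-97.3), ACGTCATC (-52.4), CAACGTCA (-33.9) and TGCGTCAT (-33.8).

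TTGCANNN also rose for CREB1 on 5hmC (1.88, adjusted p 0.00041; 12 of 64), and ETS (-0.534, 0.0082) and background with CG (-0.260, 0.033) fell. NNNCGTAA (-2.25, 0.086), TTACGNNN (-1.50, 0.12), NNNTGTCA (-0.0792, 0.77), E-box (-0.543, 0.20), A and T only (0.184, 0.64) and background without CG (0.0821, 0.51) were not called. In all, 2824 8-mers rose and 3452 fell, and 578 of these 6276 changed by at least 5 Z. The 8-mers called were 1969 and 1803 without CREB1 C replicates 1 and 2, and 1294 and 1334 without CREB1 5hmC replicates 1 and 2. Without CREB1 C replicate 2, TTGCGTCA (-11.3, 0.219), ACGTCATC (-45.2, 0.115), TGCGTCAT (-28.1, 0.110), TGACGNNN (-3.76, 0.102) and background with CG (-0.195, 0.175) were not called. The same held for TTACGTCA without CREB1 5hmC replicate 1 (-50.4, 0.0635) and for ETS without CREB1 C replicate 1 (-0.443, 0.0636). Any of 3 arrays ended the calls of TTGCGTCA, TTACGTCA, ACGTCATC, TGCGTCAT and background with CG, and any of 2 those of TGACGNNN and ETS. After normexp 5693 were called (1315 higher and 4378 lower). The groups differed in run and in spot layout, and neither can be told apart from the cytosine form.

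For CEBPB(V285A), both CRE lists fell with 5hmC. NNNCGTCA fell by 19.3 (0.186 ± 0.144 against 19.5 ± 4.29, adjusted p 1.3e-07; 60 of 64 lower, 63 adjusted over the list alone), as did TGACGNNN (difference -15.3, 4.17 ± 1.59 against 19.5 ± 4.10, 1.9e-06; 54 of 64 lower, 58 adjusted over the list alone). NNNTGCAA rose by 5.86 (8.24 ± 2.09 against 2.39 ± 0.0420, 7.4e-05; 19 of 64 higher and 1 lower, 30 and 1 adjusted over the list alone), while NNNCGCAA was not called (1.09, 0.18; 0 of 64). TTACGNNN fell by 8.30 (1.1e-06; 27 of 64), as did TTGCGNNN (-1.87, 0.0020; 12 of 64), and NNNCGTAA (-5.40, 0.00054). Without CEBPB(V285A) 5hmC replicate 2 these were -1.15 and -3.59. NNNCGTAA flipped with recomputed Z-scores (0.115) and after normexp (0.0314). TGATGCAA rose by 52.2 (97.0 ± 18.3 against 44.8 ± 4.00, 0.0016). TTACGTCA fell by 161 (6.30 ± 0.365 against 167 ± 25.0, 2.2e-07), as did TGACGTCA (difference -146, 8.62 ± 3.03 against 155 ± 27.9, 4.5e-06), TTGCGTCA (-82.3, 6.9e-08) and TTGCATCA (-11.6, 6.6e-07). TTACGTAA fell by 123 (118 ± 17.6 against 241 ± 13.2, 5.0e-07), a direction that flipped with recomputed Z-scores (6.82) and after normexp (4.27). Of the 11 fixed 8-mers 1 rose and 5 fell, also adjusted over the list alone.

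Among other called 8-mers of CEBPB(V285A), TTATGCAA (147), TTATGTAA (158 against 38.3), ATGTAATC (31.3) and TCCCCATA (50.9, 1 probe) rose most with 5hmC, and ACGTCACA (-111) and TATGACGT (-96.3) fell most. Without CEBPB(V285A) 5hmC replicate 1, TTATGCAA rose by 95.4 and TTATGTAA by 73.2, and without CEBPB(V285A) C replicate 1, TATGACGT was at -54.55. NNNTGTCA (-2.77, adjusted p 1.3e-07; 32 of 64), TGACANNN (-2.02, 5.4e-05), AP-1 (-2.15, 8.0e-06), E-box (-3.97, 6.9e-07; 41 of 48) and background with CG (-0.448, 0.0012) fell. The composite list rose (3.94, 0.0019; 5 of 30 higher and 5 lower), as did the 8-mers of A and T only (2.65 ± 0.432 against 1.36 ± 0.0674, 0.0025; 43 of 255). ETS (0.0197, 0.94) and background without CG (0.180, 0.14) were not called. In all, 1546 8-mers rose and 3209 fell, 1209 of these 4755 by at least 5 Z. Without CEBPB(V285A) C replicates 1 and 2, 2050 and 2685 were called. Recomputed Z-scores gave 5532 (2561 higher and 2971 lower). Run and cytosine form cannot be told apart in this comparison.

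For CREB1(A297V), 225 8-mers were called on 5hmC against C, 96 higher and 129 lower, 11 of them by at least 5 Z. TTACGNNN fell by 2.25 (adjusted p 0.0097; 2 of 64 lower, 8 adjusted over the list alone), as did TGACANNN (-0.789, 0.015) and AP-1 (-0.803, 0.0050). NNNCGTCA (-2.13, 0.15; 1 of 64 lower), TGACGNNN (-2.10, 0.19) and NNNCGTAA (-1.80, 0.11) were not called. None of the 11 fixed 8-mers was called, with TTACGTAA at 21.7 ± 4.17 (4 arrays) against 55.1 ± 10.8 (0.060) and TGACGTCA at 0.541 ± 0.713 (4 arrays) against 23.1 ± 0.249 (0.32). The spread was shared with the other proteins in the fit, so a missing call does not show that 5hmC changed nothing. Adjusted over the list alone, TTACGTAA (-33.4, p 0.0034) and TTACGTCA (-25.9, p 0.044) fell. Among 8-mers called over all 8-mers, the largest falls were at TTACGACA (-17.7), TTACCTAA (-11.6), TGTCGACA (-10.4), TGACGACA (-9.76) and TTACACAC (-8.54), and the largest rises at CCCTATGT (3.19), GCTTCCAC (2.77), TCCAATCT (2.60), CCAATTTT (2.59) and TCCCCATT (2.56, 3 probes). The 5hmC arrays came from 3 runs and 2 spot layouts.

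The count for CREB1(A297V) on 5hmC depended on single arrays. It was 3552 without replicate 1 and 105 without replicate 4 of CREB1(A297V) 5hmC, and 18 and 16 without replicates 1 and 2 of CREB1(A297V) C. It was 12 without either CREB1 5hmC array, 47 without either CREB1 C array, 37 and 36 without those of CEBPB(V285A) C, 39 without either of CEBPB(V285A) 5mC, 128 without either of CREB1(A297V) 5mC, and 126 and 123 without those of CEBPB 5hmC. The 5 named rises and TGACGACA (-7.56) lost their calls without CREB1(A297V) C replicate 2, as did TTACGNNN (-1.96) and AP-1 (-0.627), and TGACANNN did without replicate 1 (-0.698). Calls ended without any of 19 arrays at GCTTCCAC, 18 at CCAATTTT and TCCCCATT, 16 at CCCTATGT, 4 at TCCAATCT and 3 at TGACGACA. Recomputed Z-scores gave 38 calls (4 higher and 34 lower) and quantile normalization 473 (142 higher and 331 lower). Among the arrays of the run that held the C arrays, limma called 0 8-mers (7071 at an unadjusted p under 0.05).

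On 5hmC, CEBPB(V285A) was set against its wild type. NNNTGCAA was higher in the mutant by 6.36 (8.24 ± 2.09 against 1.88 ± 0.625, adjusted p 3.9e-05; 11 of 64, 22 higher and 1 lower adjusted over the list alone). NNNCGTAA was higher by 5.97 (8.06 ± 2.55 against 2.09 ± 0.127, 0.00025; 15 of 64, 25 adjusted over the list alone), NNNCGCAA by 5.32 (6.73 ± 1.71 against 1.41 ± 0.116, 1.4e-05; 6 of 64, 16 adjusted over the list alone), TTACGNNN by 4.62 (0.00016; 9 of 64) and the composite list by 6.47 (4.1e-05; 5 of 30). Their reverse complements TTGCGNNN (0.262, 0.63) and TTGCANNN (0.164, 0.72) were not called, and neither were NNNCGTCA (0.114, 0.96) and TGACGNNN (3.01, 0.11). At TTGCGAAA the mutant was lower (4.21 against 21.3). Of the 11 fixed 8-mers 5 were higher and 0 lower (6 and 0 adjusted over the list alone): TTACGTAA (118 ± 17.6 against 30.7 ± 10.2, 6.8e-05), TGATGCAA (97.0 ± 18.3 against 12.4 ± 9.59, 0.00013), TTACGCAA (141 ± 75.1 against 22.9 ± 5.07, 0.0072), TGACGCAA (51.4 ± 13.2 against 6.29 ± 4.87, 0.017) and TGACGTAA (134 ± 99.5 against 14.8 ± 0.210, 0.039). Without CEBPB(V285A) 5hmC replicate 1, the difference was 49.0 at TGACGTAA (189.7 without replicate 2) and 65.3 at TTACGCAA. TTGCGCAA was not called (67.3 ± 13.5 against 35.2 ± 1.01, 0.051).

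The asymmetry of CGCAA was higher in CEBPB(V285A) than in CEBPB by 5.06 (adjusted p 4.5e-08) and that of TGCAA by 6.20 (5.5e-07), while those of CGTCA (-2.90, 0.00015) and TGTCA (-1.32, 0.0073) were lower. Of called 8-mers, TTATGCAA (177 against 9.57) and TTATGTAA (147) differed most. Of those named as lower, TTGCGAAA had 19 probes, and CCCCGTCG (-21.7, flipped after normexp, 0.447), CCTCCCCG (-17.3), TCTCCCCA (-14.0) and TTCCCCTT (-13.7) had 1 each. TGACANNN (1.24, 0.0024), AP-1 (0.666, 0.033) and A and T only (0.969, 0.015) were higher, and E-box (-0.195, 0.65) and ETS (-0.154, 0.42) were not called. In all, 1255 8-mers were higher and 450 lower, and 573 and 506 were called without CEBPB 5hmC replicates 1 and 2. Without CEBPB 5hmC replicate 2, TGACGCAA (41.6, 0.143) and TGACGTAA (119.5, 0.188) were not called. TTACGCAA was not called without its replicate 1 (115, 0.0684), and neither was AP-1 (0.617, 0.123). CCCCGTCG was not called without CEBPB 5hmC replicate 2 (-14.2, 0.110), CCTCCCCG without CEBPB(V285A) 5hmC replicate 2 (-15.6, 0.0648), and A and T only (0.664, 0.140) and the TGTCA asymmetry (-0.893, 0.0748) without CEBPB(V285A) 5hmC replicate 1. That of TGACGTAA ended without any of 12 arrays, AP-1 without any of 4, TGACGCAA 3, and TTACGCAA, CCCCGTCG, A and T only and TGTCA 2. Without CEBPB(V285A) 5hmC replicate 1, the CGTCA asymmetry was -1.88 and TGACANNN 0.769, and without CEBPB 5hmC replicate 2, CCTCCCCG was -10.1. After normexp 868 were called (749 higher and 119 lower) and after quantile normalization 1530 (763 higher and 767 lower). Run and protein cannot be told apart.

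CEBPB and CREB1 on 5hmC were in 1 run with different spot layouts. CEBPB was lower at TGACGNNN (difference -8.37, 1.16 ± 0.911 against 9.53 ± 1.01, adjusted p 0.00030; 38 of 64 lower, 49 adjusted over the list alone), at NNNTGCAA (-5.82, 7.5e-05; 18 lower and 1 higher), at NNNCGCAA (-3.91, 0.00018; 8 lower) and at the composite list (-10.8, 4.6e-07; 13 of 30 lower). It was higher at TTGCGNNN by 1.56 (2.20 ± 0.444 against 0.635 ± 0.0148, 0.0070; 2 higher and 1 lower, 7 and 2 adjusted over the list alone) and at TTGCGAAA (21.3 against 0.472) and TTGCACAA (20.4). Of the 11 fixed 8-mers 2 were lower, TGATGCAA (difference -144, 12.4 ± 9.59 against 156 ± 20.6, 1.3e-06) and TGACGCAA (-70.1, 0.00062), and 0 higher (TTGCGCAA, 25.5, and TTGCGTAA, 32.4, were higher adjusted over the list alone). Lower too were ACGCAATA (-67.3), GATGACGC (-61.9) and ATGCAATA (-37.6). The asymmetries of CGCAA (-5.47, 1.6e-08) and TGCAA (-6.23, 5.4e-07) were lower and that of CGTCA higher (7.32, 1.1e-09). E-box (-2.40, 5.3e-05) and AP-1 (-1.09, 0.0017) were lower, ETS higher (0.465, 0.017), and TTGCANNN (0.410, 0.35) and NNNCGTAA (-0.590, 0.65) not called.

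Among 8-mers called over all 8-mers, the largest differences in favour of CEBPB were at TCCCCATA (44.9), CCCCGTCG (42.9) and CCTCCCCG (29.2), each with 1 probe. Of 2189 8-mers called between CEBPB and CREB1, 601 were higher and 1588 lower. The count was 1253 and 591 without CEBPB 5hmC replicates 1 and 2, and 824 and 597 without those of CREB1 5hmC. Without CREB1 5hmC replicate 2, TCCCCATA (40.3, adjusted p 0.115) and ACGCAATA (-59.8, 0.0594) were not called, and without CEBPB 5hmC replicate 2, TTGCGNNN (1.25, 0.066) and ETS (0.353, 0.139) were not. Any of 2 arrays ended the calls of TCCCCATA, ACGCAATA and ETS. After quantile normalization 3016 were called (1143 higher and 1873 lower). Spot layout and protein cannot be told apart.

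CEBPB(V285A) against CREB1 on 5hmC was lower at TGACGNNN (difference -5.35, 4.17 ± 1.59 against 9.53 ± 1.01, adjusted p 0.0074; 37 of 64 lower, 48 adjusted over the list alone). It was higher at NNNCGTAA by 5.38 (0.00055; 9 of 64), TTACGNNN by 3.33 (0.0019; 5 of 64) and TTGCGNNN by 1.82 (0.0024), but by 3.58, 2.04 and 1.10 without CEBPB(V285A) 5hmC replicate 1. Without it TTACGCAA was higher by 42.0 (148.3 without replicate 2), TTATGCAA by 97.8 and TTGCGTAA by 22.75 (not called). NNNCGCAA (1.41, 0.086) and NNNTGCAA (0.536, 0.63) were not called. TTACGTAA (118 ± 17.6 against 22.2 ± 2.80, 2.0e-05), TTGCGCAA (67.3 ± 13.5 against 9.61 ± 1.07, 0.00098), TTGCGTAA (39.5, 0.019) and TTACGCAA (95.1, 0.019) were higher, and TGATGCAA was lower (-59.0, 0.0014), which flipped with recomputed Z-scores (4.88) and after normexp (4.83). That made 4 of 11 fixed 8-mers higher and 1 lower (6 and 2 adjusted over the list alone). The composite list was lower (-4.35, 0.00093), which flipped likewise with recomputed Z-scores (0.163) and after normexp (0.455). E-box (-2.60, 2.7e-05) and NNNTGTCA (-1.12, 0.00029) were lower, and A and T only was higher (1.57, 0.00061). TTATGCAA (149) and TTATGTAA (147) were much higher, and GATGACGC (-60.2), GTGACGCA (-37.8), TGGTGACG (-30.9) and ACGCAATA (-44.7, flipped after normexp, 1.17) were lower. The asymmetries of CGTCA (4.42, 1.0e-06) and CGTAA (2.06, 0.0058) were higher.

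Of 2612 8-mers called in that comparison, 1210 were higher and 1402 lower. The count was 966 and 806 without CREB1 5hmC replicates 1 and 2, and 1703 without CEBPB(V285A) 5hmC replicate 2. TTGCGTAA (39.1, adjusted p 0.153), TTACGCAA (93.1, 0.144) and ACGCAATA (-37.2, 0.297) were not called without CREB1 5hmC replicate 2, and TGACGNNN (-4.23, 0.0629) was not without CEBPB(V285A) 5hmC replicate 2. Calls ended without any of 4 arrays at ACGCAATA, 3 at TTGCGTAA and 2 at TTACGCAA and TGACGNNN. The CGTAA asymmetry was not called without CEBPB(V285A) 5hmC replicate 1 (1.54, 0.0608). Recomputed Z-scores gave 3724 (2196 higher and 1528 lower), normexp 892 (527 higher and 365 lower) and quantile normalization 1924 (618 higher and 1306 lower). Run, layout and protein cannot be told apart.

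CREB1(A297V) against CREB1 on 5hmC was lower at TGACGNNN (-9.04, adjusted p 5.3e-05; 47 of 64), NNNTGCAA (-7.06, 4.7e-06; 35 of 64), NNNCGCAA (-4.90, 8.9e-06; 15 of 64), the composite list (-12.3, 4.5e-08; 14 of 30) and E-box (-2.79, 4.7e-06; 34 of 48). TTACGNNN (-1.72, 0.040), TTGCANNN (-1.34, 0.0017) and AP-1 (-1.41, 7.5e-05) were lower, ETS was higher (0.689, 0.00051), and NNNCGTAA was not called (-0.691, 0.55). TGATGCAA (2.51 ± 1.69, 4 arrays, against 156 ± 20.6, 8.9e-08) and TGACGCAA (4.37 ± 0.902, 4 arrays, against 76.4 ± 8.97, 7.5e-05) were lower, 2 of 11 fixed 8-mers with 0 higher, also adjusted over the list alone. ATGTGTAA (12.3), TTAGGTAA (11.7), ATTACACT (6.41), AAATTACA (5.79) and ATTTGTAA (5.59) were higher, and ACGCAATA (-73.6), GATGACGC (-65.6) and GTGACGTA (-41.7) lower. The asymmetries of CGCAA (-4.34, 4.8e-08) and TGCAA (-5.72, 2.5e-07) were lower and that of CGTCA higher (7.76, 8.5e-11). The count was 5745, 1666 higher and 4079 lower, but 1397 and 1178 without CREB1 5hmC replicates 1 and 2 and 9012 without CREB1(A297V) 5hmC replicate 4. TTAGGTAA (11.7, 0.165), GTGACGTA (-35.1, 0.257) and TTACGNNN (-1.69, 0.141) were not called without CREB1 5hmC replicate 2, and ATTTGTAA (5.45, 0.143) without replicate 1. TTACGNNN lost its call without any of 13 arrays, GTGACGTA of 3, and TTAGGTAA and ATTTGTAA of 2. Recomputed Z-scores gave 10966 (5544 higher and 5422 lower) and normexp 6176 (3744 higher and 2432 lower). Within CREB1(A297V) on 5hmC, 2493 8-mers were called between the 2 arrays of 1 run and layout and the other 2, 16 of them by at least 5 Z, and 0 of the 11 fixed 8-mers (largest difference 5.71). The Z-scores of that group were too low for this to bound a difference between runs at the high 8-mers of CREB1. Run and protein cannot be told apart.

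On 5mC, CEBPB(V285A) was higher than the single CREB1 array at NNNCGCAA by 23.1 (33.6 ± 0.808 against 10.5, adjusted p 1.1e-10; 44 of 64 higher and 2 lower, 50 and 4 adjusted over the list alone). NNNTGCAA (15.0, 1.3e-07; 34 of 64), TTGCGNNN (5.81, 1.1e-06), TTACGNNN (6.49, 5.3e-05), NNNCGTAA (4.04, 0.015) and the composite list (18.0, 3.9e-08) were higher, and NNNCGTCA was not called (-0.372, 0.88). Of the 11 fixed 8-mers 6 were higher and 0 lower (8 and 0 adjusted over the list alone): TTGCGCAA (194), TTACGTAA (72.0), TGACGCAA (163), TTACGCAA (224), TGATGCAA (162) and TTGCATCA (4.40). TTGCATCA (4.24, 0.131) and NNNCGTAA (3.75, 0.0556) were not called without CEBPB(V285A) 5mC replicate 2 (TTGCATCA also not without 6 others). Over all 8-mers 1131 were higher and 119 lower, and run and protein cannot be told apart. CREB1(A297V), in the run of the CREB1 array, was lower at NNNCGCAA (difference -8.55, 1.96 ± 0.850 against 10.5, 1.2e-06; 23 of 64, 49 adjusted over the list alone), NNNTGCAA (-3.56, 0.012), the composite list (-4.47, 0.0033) and E-box (-1.22, 0.024; not called without either CREB1(A297V) 5mC array, -1.19, 0.0695 without replicate 1). It was higher at NNNCGTAA by 3.41 (0.036; 0 of 64, 15 adjusted over the list alone), which was not called without CREB1(A297V) 5mC replicate 2 (2.05, 0.210). None of the 11 fixed 8-mers was called (1 higher and 2 lower adjusted over the list alone), and 177 8-mers were higher and 335 lower.

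Of the 100 highest 8-mers, CREB1 and CEBPB(V285A) shared 77 on C (Pearson r across 8-mers 0.852), where replicates of CREB1 shared 91 and those of CEBPB(V285A) 86, and 0.153 would be shared by chance. CREB1 and CREB1(A297V) shared 19 on C (r 0.545; replicates of the mutant 67), and the mutants shared 29 with each other. On 5mC, CREB1 and CEBPB(V285A) shared 57 (r 0.719). On 5hmC, CEBPB shared 24 with CEBPB(V285A) (r 0.552; replicates 53 and 71) and 7 with CREB1 (r 0.440; replicates of CREB1 81), and CEBPB(V285A) shared 27 with CREB1 (r 0.557). Within CREB1, C shared 15 with 5mC and 30 with 5hmC, and within CREB1(A297V) 49 and 39. The 8-mers overlap and are not independent replicates, so no p-value was attached to these. Replicate arrays correlated at r 0.335 to 0.968.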

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

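The interaction contrasts and the comparison of single arrays within a group were chosen before the data were examined, as were the tests of few probes, bright spots and a bound site elsewhere for the 8-mers with CCCC, and the remaining tests of the patterns weighed here were chosen after the result was seen.

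Only CREB1(A297V) on 5hmC had the 4 arrays needed to look for an array far from the others, by Dixon's ratio of the gap to the range. Of 35 quantities tested, 6 had such an array, 4 of them replicate 4, and chance gives about 1 in 20. At TTGCGTCA, replicate 2 was at 0.687 and the others at -0.391 to -0.337. At TTGCGTAA, replicate 4 was at 9.29 and the others at 2.02 to 3.20. NNNCGTCA was at -0.247 in replicate 3 (others -0.144 to -0.129) and TTGCGNNN at 0.660 in replicate 4 (others -0.184 to -0.0705). The asymmetries of CGCAA (-0.330, others 0.547 to 0.608) and TGCAA (-0.427, others 0.192 to 0.293) stood apart in replicate 4.

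The effect of 5mC differed between CEBPB(V285A) and CREB1 at 7 fixed 8-mers, by the interaction contrast in limma. It was larger in the mutant at TTGCGCAA (difference of the effects 130.3), TGACGCAA (124) and TGATGCAA (120.0), and smaller or more negative at TTACGTAA (-135.5), TTACGTCA (-103.1), TTGCGTCA (-53.6) and TTGCATCA (-8.93). Of these, 1 of 7 kept its direction on the 4 other scales. Lists differed at NNNCGCAA (18.76), composite (14.93), NNNTGCAA (13.14), TTGCGNNN (2.074), NNNCGTCA (-6.594), NNNCGTAA (-4.486), TTACGNNN (-3.639), E-box (-1.808), AP-1 (-1.677) and NNNTGTCA (-1.475), and 5 of 10 kept their direction on the other scales, while NNNCGTAA was called in the opposite direction after normexp (0.970, adjusted p 0.0158). Asymmetries differed at CGCAA (16.69), TGCAA (12.11) and CGTCA (-4.194), 2 of 3 with the same direction on the other scales. None of these fixed 8-mers, lists or asymmetries was called on all 4. Without CREB1 C replicate 1, NNNCGTCA (-5.54, adjusted p 0.0720), TTACGNNN (-3.07, 0.0720) and E-box (-1.46, 0.0536) were not called, and neither were TTGCGNNN without CREB1 C replicate 2 (1.86, 0.0621) and NNNCGTAA without CEBPB(V285A) C replicate 1 (-3.74, 0.0951). Any of 3 arrays ended the calls of TTGCGNNN and NNNCGTAA and any of 2 that of TTACGNNN, and NNNCGTCA was -3.56 without CEBPB(V285A) C replicate 1.

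The effect of 5mC differed between CREB1(A297V) and CREB1 at TGACGTCA (155.5). This 8-mer fell in CREB1 from 195 to 22.4 (1 array). It was also lower on 5mC in the mutant, at 5.93 against 23.1, so the lower start could account for the smaller fall. The effect of 5mC also differed at the lists NNNCGTCA (9.668), TGACGNNN (8.68), NNNCGCAA (-7.972), NNNCGTAA (4.556), NNNTGCAA (-3.559), composite (-3.555), E-box (1.484) and NNNTGTCA (0.8352), and at the asymmetries of CGCAA (-8.082), CGTAA (2.933) and TGCAA (-2.786). All of these kept their direction on the 4 other scales, but 0 of 1 fixed 8-mers, 4 of 8 lists and 2 of 3 asymmetries were called on all 4. Without CREB1(A297V) 5mC replicate 2, NNNCGTAA (3.20, adjusted p 0.105) and the CGTAA asymmetry (1.82, 0.0559) were not called. The same held for NNNTGCAA without replicate 1 of that group (-3.37, 0.0902), the TGCAA asymmetry without CREB1(A297V) C replicate 1 (-2.72, 0.101), composite without CREB1 C replicate 1 (-3.33, 0.109), and NNNTGTCA (0.588, 0.117) and E-box (1.13, 0.106) without CREB1 C replicate 2. Calls ended without any of 12 arrays at composite and the TGCAA asymmetry, 11 at NNNTGCAA, 4 at NNNCGTAA and E-box and 3 at NNNTGTCA.

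The effect of 5hmC was lower in CEBPB(V285A) than in CREB1 at TTACGTAA (-111.6), TTACGTCA (-110.2), TGATGCAA (-100.9, a smaller rise), TTGCGTCA (-65.56), TGACGCAA (-64.17) and TTGCATCA (-10.52), 3 of 6 with that direction on the 4 other scales. Lists differed at TGACGNNN (-10.21), composite (-7.388), NNNCGTCA (-7.152), TTACGNNN (-6.80), E-box (-3.432), NNNCGCAA (-2.881), NNNTGTCA (-2.693), TTGCGNNN (-1.909), TGACANNN (-1.905), AP-1 (-1.765), TTGCANNN (-1.301), A and T only (1.112) and ETS (0.554), 10 of 13 with that direction on the other scales. Asymmetries differed at CGTAA (3.653) and CGTCA (3.054). Called on all 4 other scales were 0 of 6 fixed 8-mers, 3 of 13 lists and 2 of 2 asymmetries. Without CREB1 5hmC replicate 2, TGACGCAA (-57.8), NNNCGCAA (-2.48) and TTGCANNN (-1.21) were not called. The same held without CREB1 C replicate 1 for TTGCGNNN (-1.69) and ETS (0.463), and without CEBPB(V285A) 5hmC replicate 1 for A and T only (0.806). Calls ended without any of 13 arrays at A and T only, 12 at ETS, 9 at TTGCANNN, 4 at NNNCGCAA and 3 at TTGCGNNN and TGACGCAA. Without CEBPB(V285A) 5hmC replicate 2, NNNCGCAA (-1.67) and TTGCGNNN (-1.18) were not called and the CGTCA asymmetry was 2.03, and NNNCGTCA was -4.12 without CEBPB(V285A) C replicate 1.

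Between CREB1(A297V) and CREB1, the effect of 5hmC differed at TGATGCAA (-153.0), TGACGTCA (143.7, where the mutant started at 23.1) and TGACGCAA (-60.39, not called without any of 13 arrays, such as CREB1 5hmC replicate 2, -54.0). Lists differed at composite (-11.42), NNNCGTCA (10.02), NNNTGCAA (-7.063), NNNCGCAA (-4.322), TTGCANNN (-1.552) and ETS (0.5014, not called without any of 13 arrays, such as CREB1(A297V) C replicate 2, 0.406). Asymmetries differed at CGTCA (7.043), TGCAA (-5.511) and CGCAA (-4.157). All but TGACGTCA, which was -1.40 on the asinh scale, kept their direction on the 4 other scales, but 0 of 3 fixed 8-mers, 5 of 6 lists and 3 of 3 asymmetries were called on all 4.

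The 100 highest 8-mers of CEBPB on 5hmC held 36 with CCCC, nearly all 8-mers with few probes. Those of CREB1(A297V) held 23 on 5hmC, 13 on C and 8 on 5mC, and those of every other group at most 5. Such 8-mers therefore also ranked high without CEBPB and without 5hmC. None of the 4 explanations tested was excluded. Binding of CEBPB to runs of 5hmC was open: 8-mers with CCC lay above those with GGG by 0.0997 ± 0.0274, but by 0.208 and 0.240 on the CREB1 5hmC arrays of the same run. The bound first set, the SD alone, was passed, and the comparison with CREB1 was added after these values were seen. A test on the median below was dropped, since 8-mers share probes and 0 is not the score of an unbound 8-mer. The 615 CCCC 8-mers with a probe had a median of -0.834, with 435 below 0, but means of 0.197 and 0.306 on the 2 arrays, against -0.668 and -0.459 on those of CREB1. The p-values here count 8-mers that share probes as independent. Of the CCCC 8-mers with at least 4 probes 1.59% (1 of 63) reached the 100 highest, against 6.34% (35 of 552) of those with fewer (Fisher's exact test p 0.161). Few probes may be the source, which 63 8-mers leave open. The 36 could be covered by 16 probes, between the bounds set for a few bright spots, and 18 of the 36 had 1 probe. For 11.1% (4 of 36), every probe also held another high 8-mer, against 3.80% (22 of 579) of the other CCCC 8-mers (Fisher's exact test p 0.0586), which leaves a bound site elsewhere open for those.

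TGACGTCA ranked 6 for CREB1(A297V) on C and 16145 on 5hmC, where its mean was 0.541, although its fall was not called over all 8-mers (-22.6, adjusted p 0.32). Dimmer arrays that lower every site alike were argued against: of the 100 highest 8-mers on C, the 94 that lay below TGACGTCA there would stay below it, but on 5hmC it lay under their mean (difference -4.896, SD 0.547 over the 4 arrays). A test on the proportion of the Z-score kept was made first and dropped, since the 0 of a Z-score is arbitrary. Another run alone was argued against by the 2 5hmC arrays of the run of the C arrays (0.546). Another spot layout alone was argued against by the 2 arrays with the layout of the C arrays (0.535). No 5hmC array had both the run and the layout of the C arrays, so run and layout acting in different arrays stay open. A change of scale leaves ranks as they are, and the rank was at best 6887 in any of the 4 arrays. That restates the fall in rank by which the pattern was found and is no separate test. An effect of 5hmC itself stays a hypothesis, since the pattern was found and tested on the same data, and no test made here decides it.

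The CGCAA asymmetry rose more with 5mC in CEBPB(V285A) than in CREB1 (16.7 more). After quantile normalization, which gives every array the same distribution, the difference was -1.34 (adjusted p 0.166), so the wider scale of the CEBPB(V285A) Z-scores may account for it. The other scales left it positive, called after normexp (1.99, 4.7e-05) but not with recomputed Z-scores (0.497, 0.423) or on the asinh scale (0.0171, 0.986), so this stays open. Runs holding all 4 groups numbered 0, so a difference between runs and one between the proteins cannot be told apart. The rise within each protein was not at issue in this test.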

How the results depend on the processing

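The settings chosen after seeing the data are named above. Where a value changed, the cause was not tested, except that fewer 8-mers were tested or fewer arrays fitted where the setting says so. For the values of lists that had been called, 115 of 151 kept their call and direction after normexp, 127 with recomputed Z-scores, 120 on the asinh scale, 126 after quantile normalization, 138 with a replicate block and 151 with run as a random block. For named 8-mers these were 83, 116, 84, 120, 142 and 127 of 158. Of 48 asymmetry results, 2 of which had not been called, 43, 37, 33, 41, 44 and 47 did so or stayed without a call. When 1 array was left out, 2972 of 3131 list values and 3019 of 3294 values of named 8-mers kept their call, and 0 reversed.

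Counts of called 8-mers moved by more than 1.5 times in these cases. After normexp, they were 1 (CEBPB(V285A) against CREB1 on C), 2523 (5mC in CEBPB(V285A)), 1 (5mC in CREB1(A297V)), 2959 (5hmC in CEBPB(V285A)), and on 5hmC 868 (CEBPB(V285A) against CEBPB), 892 (CEBPB(V285A) against CREB1) and 518 (CEBPB against CREB1). Recomputed Z-scores gave 240 for CEBPB(V285A) against CREB1 on C, 72 for 5mC and 38 for 5hmC in CREB1(A297V), and on 5hmC 2728 for CEBPB(V285A) against CEBPB and 10966 for CREB1(A297V) against CREB1. On the asinh scale, there were 116 for CEBPB(V285A) and 594 for CREB1(A297V) against CREB1 on C, 100, 2306 and 2 for 5mC in CREB1, CEBPB(V285A) and CREB1(A297V), 3099 and 548 for 5hmC in the mutants, and 1452 for CEBPB(V285A) against CREB1 on 5hmC. Quantile normalization gave 16 for CEBPB(V285A) against CREB1 on C, 956, 2686 and 234 for 5mC in CREB1, CEBPB(V285A) and CREB1(A297V), and 3002 and 473 for 5hmC in the mutants.

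With 7639 8-mers tested, those with a mean of at least 3 in a group, 1368 (CEBPB(V285A)) and 1537 (CREB1(A297V)) were called against CREB1 on C. For 5mC there were 1157 in CREB1 and 51 in CREB1(A297V), for 5hmC 2708 and 100, and for CREB1(A297V) against CREB1 on 5hmC 2746. A replicate block gave 64 for 5mC in CREB1(A297V), 10721 for 5hmC in CREB1, 132 for 5hmC in CREB1(A297V), and on 5hmC 3034 for CEBPB(V285A) against CEBPB, 11659 for CREB1(A297V) against CREB1 and 3508 for CEBPB against CREB1. Run as a fixed block gave 60 for 5mC in CREB1(A297V) and could not be fitted to comparisons that lie between runs. Run as a random block (correlation 0.336) gave 166 for CEBPB(V285A) against CREB1 on C, 2275 and 53 for 5mC and 1913 and 132 for 5hmC in the mutants, 955 for 5hmC in CREB1, and on 5hmC 389, 718 and 1290 for CEBPB(V285A) against CEBPB, CEBPB(V285A) against CREB1 and CREB1(A297V) against CREB1. A minimum of 8 probes gave 45 for 5mC in CREB1(A297V). Without the 2 dimmest arrays, the counts were 42 and 56 for 5mC and 5hmC in CREB1(A297V) and 3274 for CREB1(A297V) against CREB1 on 5hmC. The arrays of the CREB1 C run alone gave 295 for CREB1(A297V) against CREB1 on C, and by limma 0 for 5mC and 0 for 5hmC in CREB1(A297V), with 6256 and 7071 at an unadjusted p under 0.05.

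Leaving out 1 array gave counts of 185 to 713 for CEBPB(V285A) and 223 to 1178 for CREB1(A297V) against CREB1 on C. For 5mC they were 218 to 681 in CREB1, 2557 to 4750 in CEBPB(V285A) and 0 to 96 in CREB1(A297V), and for 5hmC 1294 to 8424, 2050 to 5730 and 12 to 3552. On 5hmC they were 506 to 2280 (CEBPB(V285A) against CEBPB), 806 to 3244 (CEBPB(V285A) against CREB1), 1178 to 9012 (CREB1(A297V) against CREB1) and 591 to 2837 (CEBPB against CREB1). A lone array left in a group was assumed to vary like the other groups. The rise of the CGCAA asymmetry with 5mC was 9.05 to 9.30 in CREB1, where only C arrays could be left out and nothing tests the single 5mC array, 25.5 to 26.2 in CEBPB(V285A) and 0.612 to 1.57 in CREB1(A297V), and with 5hmC 3.52 to 4.34, 2.47 to 3.44 and -0.313 to -0.000242. That of CREB1(A297V) with 5mC, not called in all arrays, was called after normexp (0.752, adjusted p 0.0074), with recomputed Z-scores (1.12, 0.0022), on the asinh scale (0.539, 0.0072), after quantile normalization (1.84, 0.0028) and in the arrays of its run (1.09, 0.042). With both strands averaged, CEBPB on 5hmC shared 38% of the highest 8-mers with CEBPB(V285A) and 17% with CREB1, and over the highest 500 36% and 18.4%, in place of 24% and 7%.

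Directions reversed 50 times, 26 after normexp. For CEBPB(V285A) against CREB1 on C, NNNCGTCA was -0.625 after normexp and -0.354 after quantile normalization, TGACGNNN -1.12 and -1.76, and after normexp TGACANNN was -0.156 and TTACGTCA -0.354. TGACANNN for CREB1(A297V) against CREB1 on C was 0.0793 after quantile normalization. For 5mC in CEBPB(V285A), NNNCGTAA (0.138) and TTACGTAA (0.931) reversed after normexp. With recomputed Z-scores and after normexp, NNNCGTAA (0.115, 0.0314) and TTACGTAA (6.82, 4.27) reversed for 5hmC in CEBPB(V285A), and the composite list (0.163, 0.455) and TGATGCAA (4.88, 4.83) for CEBPB(V285A) against CREB1 on 5hmC. After normexp CGATGACG (-0.574, 5hmC in CREB1), CCCCGTCG (0.447, CEBPB(V285A) against CEBPB) and ACGCAATA (1.17, CEBPB(V285A) against CREB1 on 5hmC) reversed. For CEBPB(V285A) against CREB1 on 5mC, the CGCAA asymmetry was -0.137 on the asinh scale and -1.38 after quantile normalization, that of CGTCA 0.113 recomputed and 0.958 after quantile normalization, and that of CGTAA 0.114 after normexp.

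Differences of the 5mC effect between CEBPB(V285A) and CREB1 reversed after normexp at NNNCGTCA (0.368), NNNCGTAA (0.970), TTACGNNN (0.664), TTACGTAA (6.95), TTGCGTCA (3.50) and TTACGTCA (4.10). They did so with recomputed Z-scores at composite (-0.236), TTGCGCAA (-1.83), TGACGCAA (-4.23) and TGATGCAA (-6.88), on the asinh scale at TTGCGCAA (-0.743), TTACGTAA (0.0282), TTGCGTCA (0.263) and TGATGCAA (-1.21), and after quantile normalization at NNNCGCAA (-0.913), TGATGCAA (-1.79) and the CGCAA asymmetry (-1.34). Those of 5hmC reversed after normexp at NNNCGTCA (0.0333), NNNCGCAA (0.256), TTACGNNN (0.136), TTACGTAA (9.18, recomputed 9.49), TGACGCAA (2.76) and TTACGTCA (2.50). The difference of the 5hmC effect on TGACGTCA between CREB1(A297V) and CREB1 was -1.40 on the asinh scale.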

Other observations

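The tests in this part were all chosen after the result was seen.

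Whether the modified C of GCAA alone carries the rise of NNNCGCAA with 5mC was tested by setting it against NNNTGCAA, whose core lacks the CG. NNNCGCAA rose more than NNNTGCAA in CREB1 (by 5.08, adjusted p 5.4e-08) and in CEBPB(V285A) (by 10.7, 1.2e-14), but it was also the higher list on C (1.35 against 0.535 and 5.65 against 2.39), from which a larger rise could follow. On the asinh scale neither difference was called (0.398, 0.102 and 0.278, 0.120), while both were called, in the same direction, with recomputed Z-scores, after normexp and after quantile normalization. The bound first set was the deposited scale alone, and a call on all 5 scales was required after these values were seen, so whether the modified C of GCAA is the whole cause stays open. With 5hmC the order was the opposite: NNNCGCAA rose less than NNNTGCAA in CREB1 (-3.21, 1.8e-06) and in CEBPB(V285A) (-4.77, 8.6e-09), called on all 5 scales. A candidate explanation is that 5hmC in the CG opposes the rise. This is a hypothesis that no test made here decides, since the lists differ in the base itself, T in place of C, and the same limits the test with 5mC.

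Within NNNCGCAA, 8-mers with A before the core had the highest means. For CREB1 they were at 4.14 on C and 25.3 on 5mC (1 array), against 0.119 and 4.75 with C, 0.826 and 7.28 with G, and 0.318 and 4.67 with T. For CEBPB(V285A) on 5mC the means were 76.6 with A, 33.9 with G, 12.9 with T and 10.9 with C. No test was made of these.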
